A study of Mus musculus with 167 samples.

How the data were processed

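Leukocytes were profiled by MARS-seq, a plate-based method for single cells in which each cell is sorted into a well of a 384-well plate and the 3' end of its transcripts is counted by unique molecular identifier (UMI). The 167 plates came from 23 mice. Per the labels' protocols, tumour mice (C57/b6, 10 to 12 weeks old) had 20000 cells of GL261, a mouse glioma line, implanted in the brain and were killed on day 13. Fluorescent antibodies against CD45, the common leukocyte surface protein, were injected into the blood on days 11 and 12, so that cells that were in the circulation at that time carry a stamp. Antibody against TREM2 or an isotype control was given on days 2 and 7. Brain hemispheres were perfused, digested with collagenase and DNase and cleared on Percoll, and CD45-positive cells were index sorted. Blood, gut and lung came from mice of 5 weeks without a tumour, and blood was treated by lysis of red cells in place of digestion.

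The authors deposited a table of whole-number counts per gene and well for each plate, with no normalisation, and tables that annotate wells. Per the submitters' processing notes, base calls were converted with bcl2fastq 2.15.0.4 and the genome build was mm10. The aligner, the counting program and its handling of strand and of reads with several matches are not given in the sources used here, so genes that share sequence with pseudogenes or overlap other genes are uncertain. Each table has 52634 lines, of which 92 are spike-in controls with 0 counts in all plates and stayed out, and 39121 of the 52542 gene lines had a count. The authors' annotation, as deposited, gives the mouse, the cell type or state and the time class of a well, the sequencing batch of tumour plates, and in the tissues the sorting gate and whether the mouse was stained. The time classes 12H, 24H, 36H, 48H and negative are read here as hours between stamping and harvest, with 48H used in antibody-treated and tissue mice only.

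The replicate was the mouse in every comparison. A cell was a well that the annotation lists with a cell type, and wells annotated as doublets stayed out. The cells include 3 wells of antibody plates recorded as empty. No doublet caller was run, since cells were sorted singly. This left 34753 cells. Both antibody arms were sequenced in the same batch, and the annotated untreated mice in another. Untreated tumour mouse 15 (3 plates) is not part of the annotation and enters no comparison. No pair among the 167 plates held identical counts. Summed counts of pairs of mice of a group differed by more than counting noise. The chi-square per degree of freedom was 2.23 to 3.62 in NK cells over 24 pairs and 2.84 to 39.2 in monocytes and macrophages over 30 pairs. This measure leaves out variation between cells, so it does not separate cells from mice. The annotated types were compared with 19 marker lists fixed before the data were examined. MoMac1, a group of the monocyte and macrophage annotation, matched the microglia list best (mean log2 ratio to the other types 2.29). The untreated group annotated CD4 matched the mast cell and basophil list (2.16) ahead of the CD4 T cell list (1.67), and the tissue groups annotated CD4 and Eff matched the CD8 T cell list best. The authors' names are kept throughout.

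Counts were summed over the cells of a type per mouse, or per mouse and time class, and a sum entered a test with at least 10 cells. Sums were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 after filterByExpr and TMM scaling, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Every adjusted p of a gene in the results comes from this test, and a standard error (SE) is the log2 fold change divided by the square root of F. The pool of monocytes and macrophages held the annotated monocyte, MoMac and TAM (tumour-associated macrophage) types. The time fits compared the 36H with the 12H class with the mouse as a block, the antibody fits compared 3 mice with 3, and the interaction fit compared the change from 12H to 48H between the antibody arms. The tissue fits shared a spread over the 3 tissues and had no block. Levels are CPM per mouse, counts scaled to the TMM-adjusted total of the filtered genes, given as mean ± SD, and mouse 15 and the ratios of counts use unadjusted totals. Shares of cells were tested two-sided with exact sign-flip tests within mice or exact permutation of mice. These cannot go below p = 0.125 with 4 paired mice, 0.25 with 3 paired mice and 0.1 with 3 against 3 mice. Intervals of shares are 95% exact Clopper-Pearson intervals, and these, the intervals of ratios of counts and floors (3 counts) cover counting error only. Ratios of median changes have 95% intervals from 2000 resamples of genes, a spread over genes.

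Gene lists were fixed before the data were examined, 21 in all (13 of expression programs, 6 of markers of other cell types and 2 of RNA quality), and a list was tested where at least 3 members were measured. They were tested with camera of limma 3.58.1 at a preset correlation of 0.01 and with an estimated correlation, and with fry, and p-values were adjusted over the lists of a fit. Counts of members past the test are given over all genes tested and adjusted over the list alone. The fits, their samples, the lists and the following rule for named genes were also set before the data were examined. In each comparison the rule takes genes past the test with a mean of at least 20 CPM and the same sign in every mouse, or no overlap between groups. Of these it names the 10 with the largest change in each direction, and it adds up to 4 called members of each list (or the 2 with the smallest p) and Trem2, Arg1, Gpnmb, Gzma and Gzmb. Predicted genes, receptor segments and joined gene names are excluded. The text gives a part of the genes so named.

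In the tissue mice the numbers pair the samples, since blood, gut and lung of a number come from the same animal, per the labels. The correlations of same-numbered deviations lay between -0.0604 and 0.0577 over all types together and between -0.173 and 0.131 in single types. The fit with the mouse as a block is therefore given beside a tissue result where it changes a call or moves a count by over 1.5 times.

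Plates held 111225 to 862256 counts. Median counts per cell were 1374 to 1703 in untreated mice, 746.5 to 891 in isotype mice and 964 to 1465 in anti-TREM2 mice, so depth differs between the arms. Of 656 wells recorded as empty the median was 10 counts. The fits were tested on simulated counts drawn from the real means and library sizes with 200 genes changed. In the simulated NK time fit (1023 genes) 52.2% of genes set to a log2 fold change of -1 and 100% of those set to -2 were recovered, with 2.61% of calls false. In the simulated anti-TREM2 fit of monocytes and macrophages (9317 genes) the values were 41.7%, 98.0% and 5.96%. A log2 fold change of -1 was thus often missed in these simulated fits, and smaller changes would be missed more often.

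Alternatives were RLE size factors, the Wald test of DESeq2 1.42.0, no filter and a stricter filter on low counts (10 counts), at least 20 cells per sum, only cells with at least 1000 counts, cells thinned to 1000 counts, other blocks, other sets of mice, single cell types in place of the pool and leaving out each mouse in turn. Further alternatives were chosen after seeing the data: the interaction to 36H, the antibody comparison without MoMac1 or with stamped cells alone, thinning in the antibody and isotype fits, the time course in antibody mice alone, and the antigen-presenting cell (APC) gate alone. Thinning kept only cells with at least 1000 counts and cut each to 1000. Coordinates are 1-based on GRCm38 (mm10), from GENCODE vM21. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.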

Results

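CD45-positive cells were profiled singly from brain hemispheres bearing GL261 glioma and from blood, gut and lung of mice without a tumour. The tumour mice were untreated (5 mice, 59 plates), or had received an isotype control antibody (3 mice, 35 plates) or an antibody against TREM2, a lipid-sensing receptor of macrophages and microglia (3 mice, 22 plates). Blood, gut and lung (15, 18 and 18 plates) came from the same 4 mice, of which mouse 1 was not stamped. Plates held 111225 to 862256 counts, with medians of 564883 in untreated, 290042 in isotype, 528318.5 in anti-TREM2, 169883 in blood, 424330.5 in gut and 242267.5 in lung plates. The annotated cells numbered 10584 from 4 untreated mice, 9151 from isotype mice, 6137 from anti-TREM2 mice, 2083 from blood, 3857 from gut and 2941 from lung. The design asks how immune cells change with hours spent in the tumour, what an anti-TREM2 antibody does to them, and how stamping reads out in other tissues.

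NK cells that were stamped longer before harvest held less RNA of several killing and circulation genes. From the 12H to the 36H class of untreated mice, Gzma (granzyme A, a protease of cytotoxic granules, chromosome 13, 113093825 to 113100981, minus strand) fell from 37460 ± 11053 to 17316 ± 4736 CPM (mean ± SD, n = 4 mice), a log2 fold change of -1.10 ± 0.15 (SE; adjusted p = 1.9e-05). Perforin, encoded by Prf1 (chromosome 10, 61297833 to 61304680, plus strand), fell from 2610 ± 488 to 1284 ± 708 CPM. Klrg1, an inhibitory receptor of mature NK cells (chromosome 6, 122270596 to 122282882, minus strand), fell from 533 ± 68.1 to 27.1 ± 31.3 CPM, and the chemokine Ccl5 (chromosome 11, 83525778 to 83530518, minus strand) from 41672 ± 6666 to 15003 ± 5923 CPM. Among genes that rose, the chemokine Xcl1 (chromosome 1, 164931644 to 164935527, minus strand) went from 563 ± 321 to 1139 ± 274 CPM and Ctla2a, a protease inhibitor, from 986 ± 347 to 1809 ± 348 CPM.

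Of 1147 genes tested over 1091 NK cells in the 12H and 190 in the 36H class, 80 rose and 40 fell. The cytotoxic effector list had 12 measured members, of which 7 fell and none rose (10 fell adjusted over the list alone; median log2 fold change -0.72; camera adjusted p = 9.9e-13; adjusted p = 0.0507 with an estimated correlation). Besides Gzma, Prf1 and Ccl5 these included Ccl4 (log2 fold change -1.71 ± 0.19, adjusted p = 2.2e-07), Ccl3 and Gzmb (-0.79 ± 0.16, adjusted p = 0.00091). The list of circulating NK cells had 10 members, of which 5 fell (6 adjusted over the list alone; camera adjusted p = 5e-06; adjusted p = 0.219 with an estimated correlation). They included Ly6c2 (-2.14 ± 0.32), the transcription factor gene Klf2 (-1.93 ± 0.59) and the chymase gene Cma1, with 410 counts in the 12H and 2 in the 36H class (ratio of CPM 0.0237, interval 0.00286 to 0.0862). Of 6 members of the TGF-beta and tissue residency list, Xcl1 and Ctla2a rose (2 adjusted over the list alone; camera adjusted p = 0.308), and of 3 immune checkpoint genes none passed the test (0 adjusted over the list alone), with Tigit at a log2 fold change of 0.89 ± 0.38 (adjusted p = 0.15). In the pro-inflammatory list, Ccl3 and Ccl4 fell among 4 members (2 adjusted over the list alone; camera adjusted p = 0.0016; adjusted p = 0.219 with an estimated correlation). Of 36 ribosomal protein genes, a set chosen after the data were seen, 16 rose (2 of 35 with thinned cells). Of 42 ribosomal pseudogenes 18 rose as well, so single names such as Rpl22 (1.47 ± 0.29) remain uncertain. The libraries were small, 10739 to 543699 counts. Without mouse 8 the count fell to 12 genes, without mouse 3 to 55 and without mouse 7 to 66. Without mouse 8 the adjusted p was 0.0509 for Gzmb and Ly6c2, 0.0680 for Ctla2a, 0.0737 for Prf1 and 0.356 for Xcl1. Without mouse 7 it was 0.183 for Ccl3, 0.143 for Klf2 and 0.0521 for Xcl1. It was 0.342 for Ccl3 without mouse 3 and 0.0751 for Klf2 without mouse 2. With cells of at least 1000 counts, 0 genes passed edgeR's test (207 at an unadjusted p under 0.05).

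**Figure D1:**
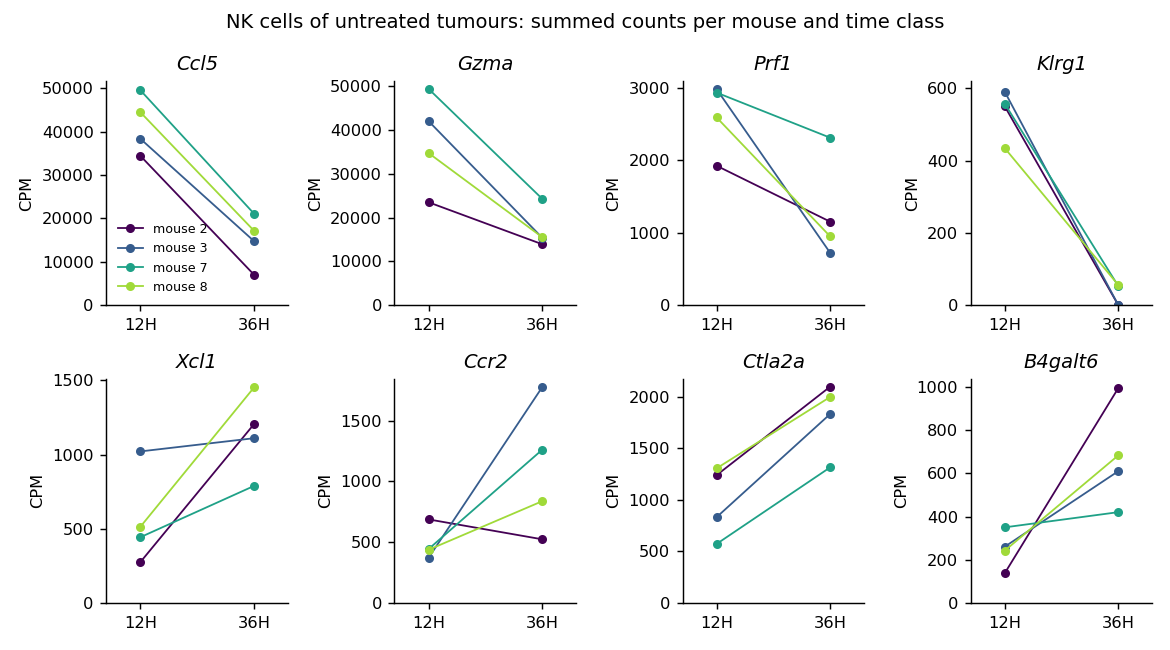
CPM (y axis) of 8 genes in NK cells of untreated tumours at the 12H and 36H classes (x axis), with a line per mouse (2, 3, 7 and 8). Ccl5, Gzma, Prf1 and Klrg1 were lower at 36H in all 4 mice, Klrg1 at 0 counts in mice 2 and 3, and Ccr2 was lower in mouse 2 and higher in the other mice.

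The annotated states of NK cells shifted with the time class in the same direction. Dysfunctional NK cells, as the authors named them, made up 34.8% ± 7.24 of NK cells in the 12H class and 78.5% ± 9.10 in the 36H class (SD, n = 4), with values per mouse of 38.5, 40.2, 24.2 and 36.4% at 12H and 80.0, 83.9, 65.2 and 84.9% at 36H. Chemotactic NK cells went from 39.2% ± 9.41 to 7.06% ± 7.28. Over the 24H class, dysfunctional cells were at 68.6% and chemotactic cells at 7.55%. Each difference had the same sign in 4 of 4 mice, and the exact p of 0.125 (adjusted 0.214) is the smallest that 4 pairs allow. Over all 10 tumour mice, which include the antibody arms, dysfunctional NK cells rose from 21.0% ± 13.3 to 66.1% ± 13.4 (higher in 10 of 10 mice; exact p = 0.00195, the smallest possible, adjusted 0.00781). The sets of states differ, since cytotoxic NK cells are annotated in untreated mice alone and intermediate NK cells in antibody mice alone, so levels cannot be compared between those sets. The states were named by the authors from expression in these cells, so they are not independent of the genes above.

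**Figure D2:**
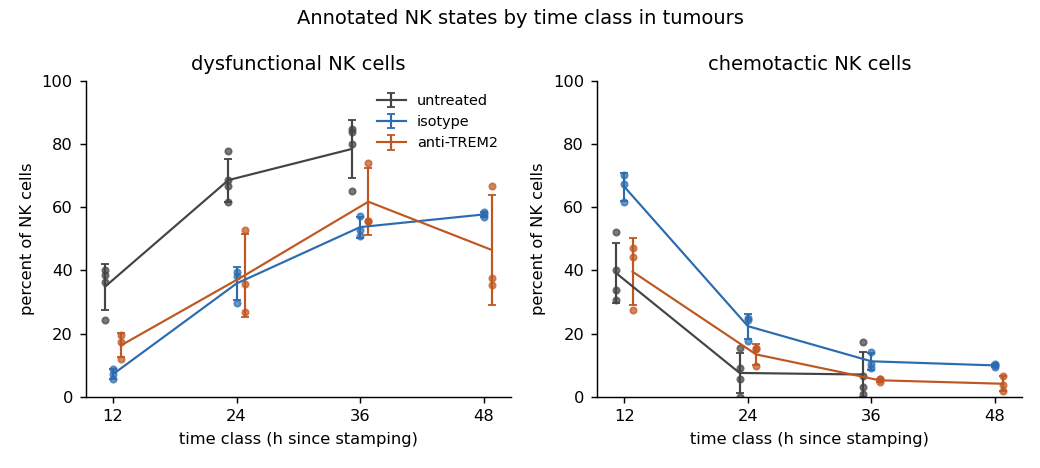
Percent of NK cells annotated as dysfunctional (left) or chemotactic (right) against the time class in hours, for untreated, isotype and anti-TREM2 tumours. Points are mice, and lines and bars are the mean and SD per group. Untreated and antibody mice were annotated with different sets of NK states. In untreated mice the dysfunctional share was 34.8% at 12 h and 78.5% at 36 h, and in isotype mice the chemotactic share was 66.5% at 12 h and 11.2% at 36 h.

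CD8 T cells, the other type with enough cells (254 in the 12H and 68 in the 36H class of 3 untreated mice), also held less Gzma and Ccl5 in the later class. Gzma fell from 3202 ± 1941 to 588 ± 552 CPM (log2 fold change -2.43 ± 0.30, adjusted p = 2.1e-06) and Ccl5 from 45553 ± 15320 to 23222 ± 2101 CPM (-0.92 ± 0.21, adjusted p = 0.044). These were the 2 genes past the test among 776, and Gzmb had a log2 fold change of -0.57 ± 0.23 (adjusted p = 0.46). The cytotoxic effector list had 2 of 10 members lower (4 adjusted over the list alone; camera adjusted p = 3.9e-06; adjusted p = 0.412 with an estimated correlation). With 1 mouse fewer the calls were 6 without mouse 3 and 0 without mouse 7 or mouse 8 (51 and 32 genes at an unadjusted p under 0.05). Gzma then had an adjusted p of 0.162 and 0.83, and Ccl5 of 0.751 and 0.83.

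In monocytes and macrophages of untreated tumours, 5 genes were lower in the 36H class, calls that depend on single mice. Nr4a1, a transcription factor needed by patrolling monocytes (chromosome 15, 101254269 to 101274795, plus strand), fell from 89.1 ± 36.5 to 13.2 ± 8.57 CPM (log2 fold change -2.69 ± 0.44, adjusted p = 0.016, n = 4), and Adgre4, an adhesion receptor of monocytes (chromosome 17, 55749984 to 55853662, plus strand), from 65.2 ± 40.8 to 10.1 ± 5.00 CPM (-2.57 ± 0.50, adjusted p = 0.036). Ifitm6 fell from 192 ± 48.4 to 67.6 ± 35.6 CPM, the haptoglobin gene Hp from 204 ± 56.0 to 93.4 ± 11.9 and Wfdc17 from 1470 ± 357 to 964 ± 286. The MHC class II genes H2-Eb1 (0.50 ± 0.11, adjusted p = 0.071) and H2-Ab1 (0.44 ± 0.10, adjusted p = 0.12) had positive log2 fold changes that did not pass over all genes. Trem2 (0.14 ± 0.21), Arg1 (-0.11 ± 0.18) and Gpnmb (-0.70 ± 0.58), all genes of tumour macrophages, did not pass either (adjusted p = 0.94, 0.95 and 0.85).

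These 5 genes that fell, with 0 that rose, were the calls among 4453 genes (285 at an unadjusted p under 0.05) over 3042 and 311 cells. Of 16 measured genes of the classical monocyte list 2 fell (5 adjusted over the list alone; camera adjusted p = 7.5e-09; adjusted p = 0.329 with an estimated correlation). In the MHC class II list, of 11 genes, 0 passed over all genes and 6 rose adjusted over the list alone (camera adjusted p = 1.1e-08; adjusted p = 0.329 with an estimated correlation). The pro-inflammatory list of 13 genes had 0 calls (0 adjusted over the list alone; camera adjusted p = 0.0017, direction down; adjusted p = 0.549 with an estimated correlation). Other lists did not pass, among them the 18 genes of the lipid and TREM2 macrophage list (0 calls; adjusted p = 0.0726) and 6 microglia markers (0 calls; adjusted p = 0.0675). The TAM share of the pool was 38.6% ± 19.6 at 12H and 57.5% ± 20.6 at 36H (higher in 4 of 4 mice; exact p = 0.125). The calls rest on single mice. In all, 0 genes passed edgeR's test without mouse 7 (247 at an unadjusted p under 0.05), 2 without mouse 3 and 29 without mouse 2. The adjusted p without mouse 7 was 0.472 for Nr4a1 and Ifitm6, 0.863 for Adgre4, 0.623 for Hp and 0.423 for Wfdc17. Without the mouse block 0 genes passed (143 at an unadjusted p under 0.05), and DESeq2 called 3.

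Among all cells of a time class, untreated tumours had a lower share of monocytes and macrophages in the 36H class, 44.9% ± 10.7 against 60.7% ± 10.4 (lower in 4 of 4 mice). NK cells were at 19.8% ± 9.89 and 25.3% ± 8.38, and regulatory T cells, which restrain other T cells, at 1.5% ± 1.22 and 4.93% ± 1.94 (both higher in 4 of 4 mice). CD8 T cells were at 6.53% ± 2.26 and 11.4% ± 5.11 (higher in 3 of 4 mice, exact p = 0.25). For the others the exact p was 0.125, the smallest possible, and 0.214 after adjustment over 12 shares. Over all 10 tumour mice regulatory T cells went from 1.27% to 3.04% (higher in 9 of 10 mice; exact p = 0.00977, adjusted 0.0293) and migratory dendritic cells (DC) from 0.826% to 1.90% (exact p = 0.0156, adjusted 0.0375). NK cells went the other way there, from 29.1% to 26.7% (higher in 5 of 10 mice; exact p = 0.396). Monocytes and macrophages went from 45.6% to 34.8% (lower in 7 of 10 mice; exact p = 0.0703).

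Monocytes and macrophages of anti-TREM2 mice differed from those of isotype mice in many genes. Arg1 (arginase 1, an enzyme of suppressive macrophages, chromosome 10, 24915221 to 24927484, minus strand) fell from 715 ± 129 to 18.3 ± 28.3 CPM (log2 fold change -5.85 ± 0.71, adjusted p = 6.9e-05, n = 3 and 3 mice), and the chemokine gene Ccl8 from 1485 ± 730 to 47.8 ± 67.7 CPM. Genes of microglia, the resident macrophages of the brain, rose: Cx3cr1 (fractalkine receptor, chromosome 9, 119901616 to 120069879, minus strand) from 71.6 ± 34.8 to 313 ± 25.1 CPM (2.11 ± 0.29, adjusted p = 0.00018) and Gpr34 (chromosome X, 13632089 to 13640858, plus strand) from 4.98 ± 2.42 to 56.9 ± 21.9 CPM (3.35 ± 0.39, adjusted p = 5.6e-05). Hes1, a target of Notch signalling (chromosome 16, 30064384 to 30067796, plus strand), rose from 11.2 ± 1.35 to 127 ± 15.7 CPM. Trem2 itself (chromosome 17, 48346401 to 48354147, plus strand) was at 210 ± 32.7 and 212 ± 68.4 CPM (0.02 ± 0.22, adjusted p = 0.97), and Gpnmb at 208 ± 107 and 127 ± 36.3 CPM (-0.69 ± 0.31, adjusted p = 0.19).

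In this fit 410 genes rose and 409 fell of 9606 tested, over 3107 isotype and 2079 anti-TREM2 cells. The hypoxia and glycolysis list changed as a block, with 19 of 21 members lower and none higher (21 adjusted over the list alone; median log2 fold change -1.79; camera adjusted p = 3.3e-48, and 0.0183 with an estimated correlation). Bnip3, a mitophagy receptor induced by low oxygen (chromosome 7, 138890836 to 138909519, minus strand), fell from 233 ± 11.5 to 26.7 ± 7.49 CPM, the triosephosphate isomerase gene Tpi1 from 682 ± 7.71 to 114 ± 17.5 CPM and Ndrg1 from 40.2 ± 15.9 to 4.97 ± 2.97 CPM. Of 13 microglia markers 11 rose (12 adjusted over the list alone; median 1.97; camera adjusted p = 6.7e-24, and 0.0438 with an estimated correlation), among them Siglech (2.48 ± 0.31) and Fcrls (3.18 ± 0.35). MoMac1 cells, whose markers match microglia, were 1.76% ± 1.51 of the isotype and 21.4% ± 7.26 of the anti-TREM2 pool. The TGF-beta and tissue residency list had 6 of 17 members higher (10 higher and 2 lower adjusted over the list alone; camera adjusted p = 1.3e-05, and 0.0438 with an estimated correlation), among them the receptor gene Tgfbr1 (343 ± 26.5 to 935 ± 32.8 CPM) and Gpr183, an oxysterol receptor (2.25 ± 0.25).

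Other lists moved in both directions. The interferon response list had 9 members higher and 7 lower of 32 (13 and 8 adjusted over the list alone; camera adjusted p = 0.216), with Ifit3b up (1.83 ± 0.28) and the GTPase genes Gbp2 (-1.65 ± 0.28) and Iigp1 (-1.89 ± 0.31) down. In the immunosuppressive macrophage list 2 of 19 rose and 5 fell (4 and 8 adjusted over the list alone; camera adjusted p = 0.172, direction down, though the median log2 fold change was 0.29). Of 5 immune checkpoint receptors and regulators 3 rose and 1 fell (3 and 1 adjusted over the list alone; camera adjusted p = 0.152). The ligand genes Cd274 (163 ± 16.1 to 47.0 ± 18.5 CPM) and Pdcd1lg2 (48.1 ± 22.1 to 4.46 ± 0.802 CPM), which are not in that list, fell. Of the lipid and TREM2 macrophage list 5 of 22 rose and 2 fell (6 and 3 adjusted over the list alone; camera adjusted p = 0.153), with Cd9 (1.85 ± 0.27) and Lpl, lipoprotein lipase (3.73 ± 0.58), up. Of 18 classical monocyte genes 1 rose and 6 fell (6 and 8 adjusted over the list alone; camera adjusted p = 0.153). Signs of handling and of other cells moved as well. Of the dissociation stress list 8 of 17 genes rose and 1 fell (10 and 1 adjusted over the list alone; camera adjusted p = 0.00015; adjusted p = 0.138 with an estimated correlation). Of 10 mitochondrial genes 2 rose (5 adjusted over the list alone; camera adjusted p = 0.016; adjusted p = 0.639 with an estimated correlation). The endothelial genes Flt1 and Pecam1 fell among 3 measured (2 adjusted over the list alone; camera adjusted p = 0.0024; adjusted p = 0.123 with an estimated correlation). The median count per cell in this pool was 1159 in isotype and 1996 in anti-TREM2 mice. With 1 mouse fewer the number of calls was 503 without anti-TREM2 mouse 3, 1252 without anti-TREM2 mouse 9 and 493 without isotype mouse 12, and 536 when cells were thinned to 1000 counts.

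**Figure D3:**
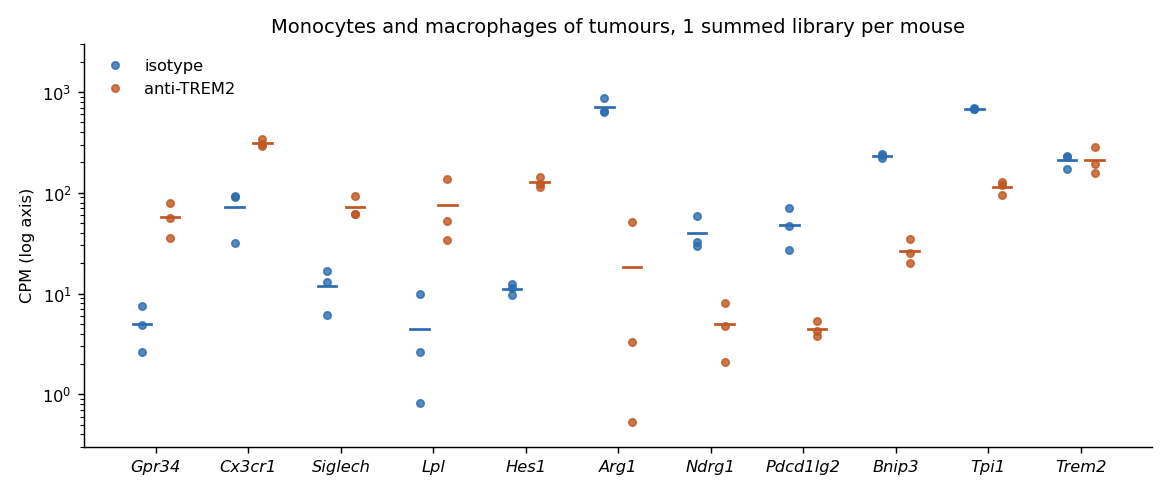
CPM (log axis) of 11 genes in monocytes and macrophages of isotype and anti-TREM2 tumours. Points are mice (3 per arm) and short bars are means. For all genes but Trem2 the arms do not overlap. Arg1 had a mean of 715 CPM in isotype and 18.3 CPM in anti-TREM2 mice, and Trem2 of 210 and 212 CPM.

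NK cells of anti-TREM2 mice had higher levels of some interferon-response genes than those of isotype mice and less Ifitm1 and Ifitm2. Ifit3, an interferon-induced antiviral gene (chromosome 19, 34583531 to 34588731, plus strand), rose from 104 ± 21.3 to 282 ± 86.4 CPM (log2 fold change 1.43 ± 0.23, adjusted p = 0.00084, n = 3 and 3) and the chemokine Cxcl10 from 83.0 ± 15.9 to 243 ± 103.4 CPM. Xcl1 rose from 1038 ± 244 to 2663 ± 821 CPM (1.37 ± 0.18, adjusted p = 3.8e-05). Ifitm1 (chromosome 7, 140967221 to 140969825, plus strand) fell from 73.1 ± 18.9 to 3.98 ± 3.53 CPM (-3.83 ± 0.51, adjusted p = 3.5e-05) and Ly6a from 490 ± 155 to 95.9 ± 26.1 CPM. Gzma (-0.36 ± 0.16, adjusted p = 0.42) and Gzmb (-0.59 ± 0.16, adjusted p = 0.085) did not pass the test.

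In NK cells 33 genes rose and 17 fell of 6837. Of 30 interferon response genes 6 rose and none fell (14 adjusted over the list alone; camera adjusted p = 4.9e-18; adjusted p = 0.0989 with an estimated correlation). Ifitm1, Ifitm2 and Ly6a, which fell, are not members of that list. The TGF-beta and tissue residency list had 4 of 20 higher (8 adjusted over the list alone; camera adjusted p = 1.3e-07; adjusted p = 0.0642 with an estimated correlation). Of 17 hypoxia and glycolysis genes none passed over all genes and 4 fell adjusted over the list alone (camera adjusted p = 0.00019; adjusted p = 0.0989 with an estimated correlation). Dissociation stress genes moved with these groups, with 2 of 12 higher (8 adjusted over the list alone; camera adjusted p = 2.2e-07; adjusted p = 0.0963 with an estimated correlation), as did 2 of 5 pro-inflammatory genes (4 adjusted over the list alone; camera adjusted p = 6.2e-06; adjusted p = 0.0642 with an estimated correlation). The number of calls was 21 without anti-TREM2 mouse 3, 100 without anti-TREM2 mouse 9, and 24 without isotype mouse 10 or without isotype mouse 14. It was 18 when cells were thinned to 1000 counts and 26 with cells of at least 1000 counts.

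Over the 8 other types with enough cells in all 6 mice, 537 calls were made in 15528 tests, 241 up and 296 down, most in conventional DC2 (130 up, 194 down) and CD4 T cells (70 up, 35 down). In DC2, Epcam, an adhesion molecule of Langerhans-type cells, rose from 6.28 ± 2.07 to 342 ± 65.2 CPM (log2 fold change 5.66 ± 0.43, adjusted p = 1.6e-07) and the integrin gene Itgae from 21.8 ± 15.2 to 197 ± 42.0 CPM. Ccr7, the receptor that guides DC to lymph nodes, fell from 479 ± 106 to 99.8 ± 85.2 CPM and Cd274 from 236 ± 82.1 to 25.6 ± 7.94 CPM. In CD4 T cells the interferon-induced Slfn5 rose from 380 ± 106 to 1394 ± 225 CPM (1.88 ± 0.24, adjusted p = 3.1e-05) and Gzma fell from 1523 ± 826 to 267 ± 174 CPM. Gzma fell in CD8 T cells too, from 2673 ± 456 to 1197 ± 34.8 CPM (-1.15 ± 0.17, adjusted p = 0.00019), and Gzmb in regulatory T cells from 4116 ± 249 to 745 ± 235 CPM (-2.49 ± 0.42, adjusted p = 0.00091).

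The hypoxia and glycolysis list was lower in several of these types. It had 5 of 13 members lower in DC2 (9 adjusted over the list alone; camera adjusted p = 2.8e-09, and 0.0374 with an estimated correlation). It had 4 of 9 lower in CD4 T cells (7 adjusted over the list alone; 5e-09, and 0.045 with an estimated correlation) and 4 of 8 in MonDC (7 adjusted over the list alone; 4.5e-14; adjusted p = 0.102 with an estimated correlation). The interferon response list went up in CD4 T cells (10 of 28; 20 adjusted over the list alone; camera adjusted p = 1.1e-17; adjusted p = 0.161 with an estimated correlation) and down in DC2 (9 of 32; 13 adjusted over the list alone; camera adjusted p = 2.1e-05; adjusted p = 0.387 with an estimated correlation). The difference between the types was not tested. Dissociation stress genes rose as well, 4 of 16 in DC2 (6 adjusted over the list alone; camera adjusted p = 0.00088; adjusted p = 0.312 with an estimated correlation). In CD4 T cells 2 of 11 did (3 adjusted over the list alone; camera adjusted p = 0.00013; adjusted p = 0.0903 with an estimated correlation). In MonDC the mitochondrial list was higher (9 of 9 positive; 0 calls over all genes or the list alone; camera adjusted p = 0.0349; adjusted p = 0.554 with an estimated correlation). The calls over these types came to 291 without anti-TREM2 mouse 3, 289 without anti-TREM2 mouse 5, 849 without anti-TREM2 mouse 9, 298 without isotype mouse 10 and 292 without isotype mouse 12.

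Cell type shares differed between the antibody arms with no overlap between mice for several types. CD8 T cells made up 8.42% ± 3.01 of isotype and 21.7% ± 6.20 of anti-TREM2 cells, conventional DC1, which cross-present antigen, 0.769% ± 0.216 and 3.78% ± 1.43, DC2 6.06% ± 1.33 and 8.91% ± 0.758, and NK cells 34.7% ± 7.19 and 18.8% ± 2.52 (n = 3 and 3). Migratory DC were at 3.95% ± 1.32 and 1.89% ± 0.559. The pool of monocytes and macrophages was at 34.3% ± 6.87 and 33.8% ± 0.666 (exact p = 1), but its makeup differed: Arg1 TAM were 42.9% ± 4.86 and 1.43% ± 1.02 of the pool, Gpnmb TAM 8.14% ± 2.72 and 0.556% ± 0.558, and Acp5 TAM 3.59% ± 0.935 and 49.5% ± 17.2. These states are named after genes that differ between the arms, so their shares are not independent of the gene changes. Dysfunctional NK cells were at 40.5% and 40.4% of NK cells over all classes (exact p = 1). Within the 12H class they were at 7.18% ± 1.54 and 16.3% ± 3.88, and chemotactic NK cells at 66.5% ± 4.45 and 39.6% ± 10.5, differences that were not tested. Where the arms did not overlap, the exact permutation p was 0.1 (adjusted 0.142), the smallest that 3 against 3 mice allow, and chance alone separates the arms in 10% of cases.

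The change of monocytes and macrophages from the 12H to the 48H class could be set against treatment in few mice, since a single anti-TREM2 mouse (mouse 5) and the isotype mice 12 and 14 had at least 10 cells in both classes (252 and 16 cells in mouse 5, 188 and 49 in mouse 12, and 122 and 26 in mouse 14). The lone mouse is assumed to vary like the others, with 1 residual degree of freedom. An effect of treatment therefore cannot be told apart from that mouse. Of 1778 genes 4 passed, all with a more positive change in the anti-TREM2 mouse. Cxcl10 went from 947.8 to 2150 CPM in the anti-TREM2 mouse and from 1053 to 510.3 and 602 to 311.7 CPM in the isotype mice (interaction log2 fold change 2.19 ± 0.54, adjusted p = 0.026). Tnfaip2 went from 154.5 to 537.6 CPM, against 561.5 to 139.2 and 612.4 to 450.2 (3.02 ± 0.75). Ifitm1, near 0 in the anti-TREM2 mouse at 12H (2.09 CPM), had no stable direction (5.17 ± 1.28, but -2.29 with cells of at least 1000 counts). Pou2f2 was at 139.9 and 307.2 CPM in the anti-TREM2 mouse and went from 187.2 and 249.1 CPM to 0 in the isotype mice, so its size is not given. DESeq2 called 0 genes (17 at an unadjusted p under 0.05). The test of edgeR called 0 with no filter (343) or the stricter filter (201) and 1 with 36H as the later class or with cells of at least 1000 counts.

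Isotype mice were compared with untreated mice as a background for the antibody arms, and monocytes and macrophages differed in few genes. The immediate early transcription factor genes Egr1 and Egr2 were lower in isotype mice, Egr1 at 143 ± 14.5 CPM in untreated (n = 4) and 34.3 ± 14.1 in isotype mice (n = 3; log2 fold change -2.05 ± 0.24, adjusted p = 0.022) and Egr2 at 74.0 ± 7.04 and 27.5 ± 6.76 CPM. The adhesion gene Vcam1 (chromosome 3, 116109949 to 116129688, minus strand) fell from 34.8 ± 14.9 to 6.57 ± 1.3 CPM, and H2-Oa rose from 12.8 ± 3.14 to 44.7 ± 12.8 CPM. Trem2 (-0.20 ± 0.46), Arg1 (-0.13 ± 0.58) and Gpnmb (-0.62 ± 0.46) did not pass the test (adjusted p = 0.89, 0.95 and 0.61).

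In this comparison 6 genes rose and 8 fell of 10501 (1356 at an unadjusted p under 0.05). The pro-inflammatory list had 1 of 17 members lower (8 adjusted over the list alone; camera adjusted p = 3.5e-08; adjusted p = 0.272 with an estimated correlation) and the dissociation stress list, which holds Egr1, 1 of 17 (4 adjusted over the list alone; camera adjusted p = 3.7e-06; adjusted p = 0.062 with an estimated correlation). Hypoxia and glycolysis genes had 0 of 23 past the test (5 higher adjusted over the list alone; camera adjusted p = 6.2e-07; adjusted p = 0.336 with an estimated correlation). Red cell RNA differed between these libraries, with Hba-a1 at 76.63, 182.1, 1.564 and 95.48 CPM in untreated mice 2, 3, 7 and 8 and at 0 counts in all isotype mice. The untreated and the isotype mice were sequenced in different batches, so batch and antibody cannot be told apart. The count was 0 without isotype mouse 10 or isotype mouse 12 (1198 and 1093 at an unadjusted p under 0.05), 1 without isotype mouse 14 and 31 without untreated mouse 2, and 0 with cells of at least 1000 counts (1195) or thinned cells (842). DESeq2 called 119. Without isotype mouse 10 the adjusted p was 0.0786 for Egr1, 0.159 for Egr2, 0.178 for Vcam1 and 0.0962 for H2-Oa.

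In mice without a tumour the stamp separated the tissues. Nearly all annotated blood cells of the 3 stamped mice carried a time class (98.8% ± 0.955, SD), against 70.6% ± 0.47 in gut and 82.1% ± 7.12 in lung. In the unstained mouse 12 of 1416 cells did (0.847%, exact 95% interval 0.439 to 1.48%). The difference was -28.2 percentage points for gut and -16.7 for lung against blood (exact p = 0.25, the smallest that 3 pairs allow). The gate matters for these values: in the APC gate alone they were 98.0% ± 1.84, 43.1% ± 5.32 and 52.5% ± 31.7. In the other gate, named time stamp, 86.7 to 100% of cells were stamped, and the blood of mouse 4 gave no cells there. The tested differences pool both gates, so they depend in part on the sorting. By type within the APC gate, 349 of 528 gut cells annotated Macrophages (66.1%), 31 of 96 annotated Macrophage (32.3%), 20 of 204 gut DC (9.80%) and 3 of 73 ResT cells of the gut (4.11%) were stamped in the 3 stamped mice. Differences between types were not tested. Blood cells of the stamped mice were spread over the time classes. In mice 2, 3 and 4, 413, 368 and 73 cells were 12H and 62, 188 and 52 were 24H. Another 284, 136 and 28 were 36H, and 37, 42 and 24 were 48H. A late class therefore does not by itself mean that a cell had spent those hours in a tissue.

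**Figure D4:**
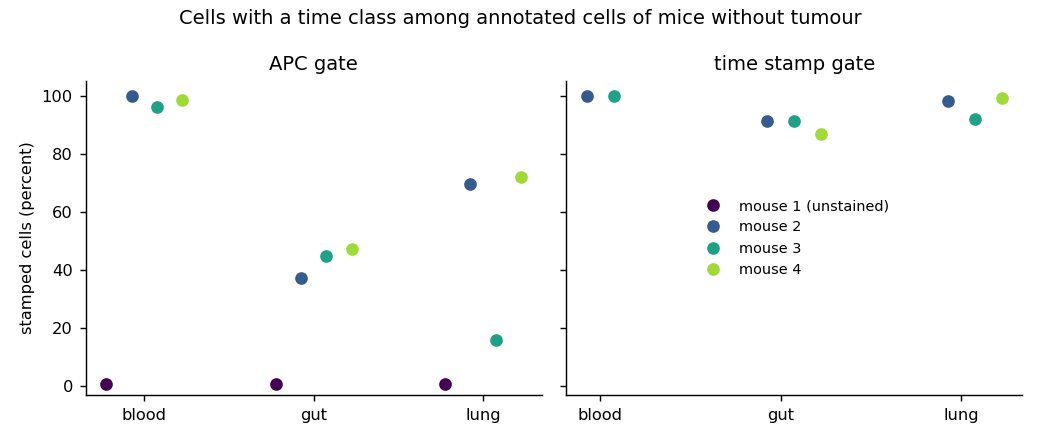
Percent of annotated cells with a time class (y axis) in blood, gut and lung of mice without a tumour, by sorting gate (panels), with a point per mouse. The unstained mouse 1 lies near 0 in all 3 tissues. In the APC gate, mean values of the stamped mice were 98.0% in blood, 43.1% in gut and 52.5% in lung, where mouse 3 had 15.9%.

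The tissues differed in their cell types in a way that was the same in 4 of 4 mice for the types named here. Cells annotated Macrophages made up 53.7% ± 7.91 of gut, 2.36% ± 1.11 of lung and none of the blood cells. A second annotation, Macrophage, which these shares leave out, held 30, 60, 66 and 63 gut and 3, 6, 7 and 10 lung cells in mice 1 to 4, and 18 blood cells in mouse 3. Neutrophils were 24.5% ± 10.3 of blood, 8.41% ± 2.79 of lung and 0.363% ± 0.131 of gut cells, and CD8 T cells 20.7% ± 1.87 of blood, 3.18% ± 1.09 of lung and 0.326% of gut cells. Monocytes were at 14.8% ± 1.87, 28.6% ± 3.83 and 1.93% ± 0.453 in blood, lung and gut. The exact p of 0.125 is the smallest that 4 pairs allow. These shares pool both sorting gates, and mouse 1 and the blood of mouse 4 had cells of the APC gate alone. In the stamped mice, gut cells annotated Macrophages numbered 528 in the APC gate and 1326 in the time stamp gate. All annotated gut cells of mice 2, 3 and 4 numbered 369, 492 and 499 in the APC gate. In the time stamp gate they numbered 606, 617 and 682. Tissue and gate are therefore not fully told apart here.

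Gut monocytes held more RNA of several inflammatory and antigen presentation genes than blood monocytes. The gut sums were small, with 57 cells annotated Monocytes in the stamped mice against 244 in blood. Of these 57 cells, 38 came from the APC gate, where 11 were stamped. Interleukin 1 beta (Il1b, chromosome 2, 129364570 to 129371139, minus strand) was at 136 ± 43.1 CPM in blood and 7200 ± 1878 CPM in gut (log2 fold change 5.63 ± 0.29, adjusted p = 3.8e-16, n = 4), Thbs1, thrombospondin 1 (chromosome 2, 118111876 to 118127133, plus strand), at 18.7 ± 13.2 and 5034 ± 1262, and H2-Ab1 at 495 ± 432 and 6652 ± 3329. In the group annotated Eff, Gzma fell from 1263 ± 1230 to 122 ± 126 CPM in gut, and Xcl1 (3.70 ± 0.67) and the transcription factor gene Ikzf2 (4.06 ± 0.40) rose. In B cells the cAMP-responsive factor Crem (chromosome 18, 3266048 to 3337748, minus strand) rose from 39.0 ± 48.4 to 919 ± 618 CPM and Cd86, a costimulatory ligand, from 50.2 ± 40.3 to 543 ± 251.

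Over 4 types, 265 genes rose and 248 fell in gut against blood (292 in all without mouse 2 and 254 with sums of at least 20 cells). In monocytes the pro-inflammatory list had 4 of 5 members higher (4 adjusted over the list alone; camera adjusted p = 1.8e-11, and 0.0147 with an estimated correlation) and the MHC class II list 6 of 9 (7 adjusted over the list alone; 1.1e-07, and 0.0287 with an estimated correlation). Gut and lung were digested and blood was not, and dissociation stress genes were higher too, 6 of 11 in gut monocytes (6 adjusted over the list alone; camera adjusted p = 5.6e-06, and 0.0298 with an estimated correlation) and 3 of 9 in gut B cells (3 adjusted over the list alone; 0.0016; adjusted p = 0.0618 with an estimated correlation and the mouse as a block). The TGF-beta and tissue residency list had 4 of 5 members higher in Eff cells (4 adjusted over the list alone; camera adjusted p = 3.9e-07, and 0.0215 with an estimated correlation).

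In lung against blood, Il1b rose to 3396 ± 269 CPM (4.54 ± 0.28, adjusted p = 5.1e-14) and Thbs1 to 2660 ± 936 CPM in lung monocytes, and in lung neutrophils the chemokine Cxcl2 went from 15.5 ± 17.9 to 1707 ± 401 CPM (6.05 ± 0.49, adjusted p = 1.2e-08) and the endotoxin co-receptor gene Cd14 from 99.1 ± 89.2 to 3930 ± 1146. Crem rose in lung B cells to 892 ± 273 CPM (5.25 ± 0.60). In lung NK cells Gzma (-0.12 ± 0.19, adjusted p = 0.95) and Gzmb (0.30 ± 0.36, adjusted p = 0.95) did not pass the test, and the G-protein regulator gene Rgs2 rose (3.29 ± 0.65, adjusted p = 0.0008).

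Over 7 types 335 genes rose and 166 fell (237 in all without mouse 2, 303 without mouse 3 and 79 with cells of at least 1000 counts). In lung monocytes 4 of 5 pro-inflammatory genes were higher (4 adjusted over the list alone; camera adjusted p = 8.8e-11, and 0.00955 with an estimated correlation) beside 6 of 11 dissociation stress genes (8 adjusted over the list alone; 2.8e-08, and 0.00955 with an estimated correlation). In lung neutrophils 7 of 8 pro-inflammatory genes rose (7 adjusted over the list alone; 3.5e-07; adjusted p = 0.0120 with an estimated correlation and 0.089 with the mouse as a block).

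Between lung and gut, monocytes of the lung held less MHC class II RNA, with H2-Eb1 (chromosome 17, 34305867 to 34316674, plus strand) at 2386 ± 900 CPM in gut and 455 ± 197 in lung (-2.41 ± 0.37, adjusted p = 0.00017), and 4 of 9 genes of the list were lower (5 adjusted over the list alone; camera adjusted p = 1.5e-07, and 0.0394 with an estimated correlation). DC of the lung held more Cd207 (langerin; 5.53 ± 0.54) and more of the chemokine gene Ccl17 (2154 ± 1165 to 12165 ± 3890 CPM; 2.49 ± 0.31, adjusted p = 6.9e-06). Eff cells of the lung held more Gzma (3.94 ± 0.63, adjusted p = 0.00037). Lung macrophages, from 4 gut and 3 lung samples, were higher in Chil3, a chitinase-like gene of alveolar macrophages (8.54 ± 0.59), and in Lpl (3.43 ± 0.39) and lower in Apoe, the apolipoprotein of many tissue macrophages (28678 ± 2351 to 14776 ± 1730 CPM). Trem2 did not pass there (-0.11 ± 0.57, adjusted p = 0.95). Over 6 types 110 genes rose and 127 fell, 138 in all with the mouse as a block, 149 without mouse 2 and 117 without mouse 3. The count was 32 with cells of at least 1000 counts, 89 with sums of at least 20 cells and 579 with no filter. In the macrophage fit the median log2 fold change of all genes was -0.416 with TMM and -0.194 with RLE, which moved it by 0.222. It was -0.0886 without scaling, so sizes in that fit depend on the scaling.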

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

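The fits without MoMac1 cells, with stamped cells alone and with thinned cells in the antibody arms, and the sets of ribosomal protein genes and pseudogenes, with their tests, were chosen only after the data were seen. Intervals of ratios come from resampled genes and do not cover differences between mice.

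Microglia marker genes were higher in monocytes and macrophages of anti-TREM2 mice, by a median log2 fold change of 2.11 over the 9 called genes that could be followed. With stamped cells alone, which leaves out unstamped resident cells, the median was 1.03 times that of the pool (interval 0.991 to 1.12). This argues against unstamped cells as the whole source. With cells of at least 1000 counts, each thinned to 1000, the median was 0.912 times (0.812 to 1.01). Over all types, such cells were 37.5% of isotype and 59.1% of anti-TREM2 cells. For the cells kept, the thinned value argues against the depth gap as the whole source. Without cells of the MoMac1 type the median was 1.82, or 0.860 times (0.662 to 1.01), and 9 of 9 genes stayed past the test, so a part carried by MoMac1 cells stays open. Of the 11 markers called in the pool, those no longer measured in this fit are left out. A gene carried mainly by MoMac1 cells could drop out in this way, so that part may be understated. The antibody itself, which the design names, stays among the open explanations.

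Genes that differed between the arms in monocytes and macrophages could also reflect plates or handling shared by all cells of an arm. If so, the same genes would move alike in other cells of the same mice. In CD8 T cells their median change was 0.285 times that in the pool (0.241 to 0.394, 270 genes, of which 209 had the same sign), and in NK cells 0.202 times (0.168 to 0.237, 432 genes, of which 307 had the same sign). The limits set before the test were a ratio of at least 0.5 for a shared cause and under 0.2 against it. Both intervals lay under 0.5. For the genes measured there, they argue against a cause that moves all cells alike as the whole source. Neither interval lay fully under 0.2, so a smaller shared part stays open. Such a part cannot be told apart from an effect of the antibody on several cell types, since both allow a smaller change of the same sign. Thinning the cells with at least 1000 counts left 0.970 times the change (0.944 to 1.00). It covered 669 genes, of which 476 still passed the test, and argues against depth for those genes and cells.

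Ribosomal protein genes were higher in NK cells of the 36H class, with 34 of 36 positive, a median log2 fold change of 0.78 against -0.02 for other genes, and a share of counts of 1.76% ± 0.145 at 12H and 2.98% ± 0.147 at 36H (higher in 4 of 4 mice). Leaving out the 50 most abundant other genes left 1.01 times the median (1.01 to 1.02). TMM scaling already corrects for a few genes taking most of the counts, so this value could hardly move and decides nothing. With no scaling, the median was 0.905 for ribosomal protein genes and 0.0911 for other genes. A few dominant genes would shift both sets alike, so these values argue against them as the whole source. Cd3 genes, at 0 counts in NK cells of the 36H class, stood at 0% of their level in CD8 T cells (up to 0.789% at the floor of 3 counts). This argues against T cells with Cd3 RNA as the source. The authors named these cells from expression, so such cells may have been kept out beforehand, and T cells without Cd3 counts are not covered. Thinning took the median of 35 genes from 0.75 to 0.46, or 0.620 times (0.547 to 0.782), and left 2 past the test on fewer counts. It also leaves out cells under 1000 counts, so depth and the choice of cells cannot be told apart there. Median counts per NK cell at 12H and 36H were 732 and 772 in mouse 2 and 793 and 666 in mouse 3. They were 1015.5 and 1089 in mouse 7 and 692 and 914 in mouse 8. The depth gap thus had no single direction, while the ribosomal share rose in 4 of 4 mice. A part from depth stays open. No biological explanation was tested.

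Other splits of the same samples were counted for each fit. In the tissue comparisons 1 of 35 splits, the real one, gave as many genes, so chance can be excluded if samples are taken as unpaired, for gut against blood (513 genes, highest other split 5), lung against blood (501 and 6) and lung against gut (237 and 9). The samples pair by mouse, however, and the 8 splits that part all 4 pairs are too few for a share under 0.05 (highest others also 5, 6 and 9). For isotype against untreated mice 3 of 35 splits gave as many as the real 14 genes. The highest gave 64, so chance cannot be excluded, and why that split gave more was not tested. The remaining designs have too few splits for a share under 0.05. Their real values and highest other splits were 5 and 2 genes for the time course of monocytes and macrophages (1 of 8 splits as large), 120 and 0 for NK cells (1 of 8) and 2 and 6 for CD8 T cells (2 of 4). For anti-TREM2 they were 819 and 0 in monocytes and macrophages, 50 and 0 in NK cells and 537 and 2 in the other types (1 of 10 splits as large in each).

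Of 177 groups of 4 to 10 mice, 12 held a mouse far from the others, against about 9 that chance alone would give (1 in 20 groups). In the change from 12H to 36H, untreated mouse 8 stood apart for conventional DC2 (9.12 percentage points, others -3.11 to -1.52). Among all tumour mice, anti-TREM2 mouse 5 did so for CD8 T cells (36.04, others -4.40 to 16.4) and anti-TREM2 mouse 3 for conventional DC1 (5.37, others -2.04 to 1.28). In NK cells the log2 ratio of Ccl5 was -2.29 in untreated mouse 2 and -1.38 to -1.23 in the others. In the tissues, B cells were 26.7% of blood cells in mouse 4 (others 16.9 to 18.4%). In mouse 1, neutrophils were 0.169% of gut cells (0.410 to 0.451%) and NK cells 3.43% of lung cells (6.82 to 7.39%). Those samples held cells of the APC gate alone, unlike most others. In the stamped mice, blood B cells numbered 251 in the APC and 70 in the time stamp gate. Gut neutrophils numbered 2 and 12, and lung NK cells 37 and 140. Mouse and gate therefore cannot be told apart for these shares. Single genes that stood apart were Thbs1 in gut monocytes of mouse 2 (3161 CPM, others 5456 to 5894), Il1rn in lung neutrophils of mouse 4 (1261 CPM, 2468 to 2703) and Ifi47 in blood CD8 T cells of mouse 4 (1125 CPM, 840 to 885.1). Ccl17 did so in gut DC of mouse 2 (414.2 CPM, 2595 to 2862) and Itgae in lung DC of mouse 1 (256.9 CPM, 53.3 to 60.5). The limit of the APC gate holds for Ifi47 and Itgae as well.

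Some changes had opposite signs in all mice of 2 groups, a difference that was not tested. From 12H to 36H the share of monocytes and macrophages changed by 10.0 percentage points in isotype mice (7.63 to 11.3), -25.0 in anti-TREM2 mice (-34.5 to -19.9) and -15.9 in untreated mice (-31.1 to -5.27). That of CD8 T cells changed by -3.07 in isotype mice (-4.40 to -0.497) and 19.5 in anti-TREM2 mice (6.10 to 36.04), and that of NK cells by 5.50 in untreated (1.76 to 8.75) and -11.5 in isotype mice (-16.0 to -4.87). The interaction fit sets a single anti-TREM2 mouse (mouse 5) against isotype mice 12 and 14 and cannot tell treatment from that mouse. It gave 4 genes by edgeR, while DESeq2 called 0 (17 at an unadjusted p under 0.05), as did edgeR with no filter (343) or a stricter filter (201). Their log2 fold changes were 2.19 for Cxcl10, 3.02 for Tnfaip2 and 5.17 for Ifitm1, which has no stable direction (-2.29 with cells of at least 1000 counts), while the fitted 9.10 of Pou2f2 is not a size, since isotype mice were at 0 counts at 48H.

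Untreated mouse 15, which has no annotation and enters no comparison, had 808 wells with at least 500 counts. A well recorded as empty on an antibody plate held 1075 counts, against a median of 9 over the 228 empty wells of those plates. The 3 such wells with at least 500 counts carry a cell type and are among the cells compared.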

How the results depend on the processing

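The fits with antibody mice only, without MoMac1 cells, with stamped cells alone, with the 36H class as the longest time, in the APC gate alone, and those thinned in the antibody and isotype comparisons were chosen only after the data were seen. Of the values for single genes under alternatives, 2174 kept their direction and their side of the threshold, 298 kept their direction but were no longer past it, 27 came to pass it and 28 changed sign. Of the counts and shares, 429 were classed as unchanged, 80 moved, 58 came to pass a test and 15 changed sign. Unchanged does not mean identical for a count of genes. Exact tests of shares cannot go below p = 0.125 with 4 paired mice, 0.25 with 3 paired mice and 0.1 with 3 against 3 mice. Shares tested in these ways could not cross the threshold, so the 429 do not measure how stable counts and shares are. The counts given below were lower with cells of at least 1000 counts. They moved in both directions with thinned cells and with 1 mouse left out. Except where a value below shows it, the cause was not tested.

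With DESeq2 the time course had 3 genes in monocytes and macrophages (5 with edgeR), 71 in NK cells (120) and 1 in CD8 T cells (2). The interaction had 0 with DESeq2 (4 with edgeR; 17 at an unadjusted p under 0.05 by DESeq2) and isotype against untreated 119 (14). RLE factors gave 6 in CD8 T cells. Without a filter on low counts, which tests more genes, these counts were 30, 10, 13, 0 (343 at an unadjusted p under 0.05 by edgeR) and 213, while anti-TREM2 in NK cells had 83 (50) and lung against gut 579 (237). A stricter filter left 0 for the interaction (201 at an unadjusted p under 0.05 by edgeR) and 1 in CD8 T cells. Sums of at least 20 cells gave 254 genes for gut against blood (513) and 89 for lung against gut.

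With cells of at least 1000 counts alone, the time course had 2 genes in monocytes and macrophages and 0 in NK cells by edgeR (207 at an unadjusted p under 0.05). Anti-TREM2 had 26 in NK cells, the interaction 1, isotype against untreated 0 by edgeR (1195 at an unadjusted p under 0.05), lung against blood 79 (501) and lung against gut 32. Cells thinned to 1000 counts gave 8 and 20 for the time course, 536 (819) and 18 for anti-TREM2, and 0 for isotype against untreated by edgeR (842 at an unadjusted p under 0.05). With the 36H class as the longest time the interaction had 1 gene.

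For the time course of monocytes and macrophages, all tumour mice gave 138 genes, antibody mice only 158, inflammatory monocytes alone 1, and MoMac and TAM alone 0 each by edgeR (41 and 106 at an unadjusted p under 0.05). NK cells had 319 in all tumour mice and 226 in antibody mice only. For anti-TREM2, single types gave 1 gene in monocytes, 32 in MoMac1, 108 in MoMac2, 103 in Acp5 TAM and 131 in Arg1 TAM, each tested on fewer cells. With an estimated correlation, the lists past camera's threshold went from 3 to 0 for the time courses of monocytes and macrophages and of NK cells, 1 to 0 for that of CD8 T cells, 6 to 3 and 6 to 0 for anti-TREM2 in monocytes and macrophages and in NK cells, 4 to 0 for the interaction and 7 to 0 for isotype against untreated.

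Leaving out 1 mouse gave 0 to 29 genes for the time course of monocytes and macrophages (0 without mouse 7, where 247 had an unadjusted p under 0.05 by edgeR), 12 to 88 for NK cells and 0 to 6 for CD8 T cells (0 without mouse 7 or 8, with 51 and 32 at an unadjusted p under 0.05 by edgeR). It gave 493 to 1252 for anti-TREM2 in monocytes and macrophages, 21 to 100 in NK cells and 289 to 849 in the other types, with the highest without anti-TREM2 mouse 9 in each. Isotype against untreated had 0 to 31 (0 without isotype mouse 10 or 12, with 1198 and 1093 at an unadjusted p under 0.05 by edgeR). The tissues had 292 to 502 for gut against blood, 237 to 477 for lung against blood and 117 to 262 for lung against gut.

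Pairing by mouse was an option in 2 kinds of fit. Without the block of mice the time course of monocytes and macrophages had 0 genes by edgeR (143 at an unadjusted p under 0.05), and Arg1 was at 0.058 in place of -0.11. With a block in the tissue fits, gut against blood had 465 genes, lung against blood 417 and lung against gut 138, and 2 named genes no longer passed, Srgn in lung against blood CD8 T cells (adjusted p = 0.111) and Stab1 in lung against gut macrophages (adjusted p = 0.369). Lists that no longer passed with the block were dissociation stress in gut against blood B cells (adjusted p = 0.0618 with an estimated correlation), circulating NK, classical monocyte (camera adjusted p = 0.0537 each) and mitochondrial RNA (0.0543) in gut against blood CD4, and pro-inflammatory in lung against blood neutrophils (0.0890 with an estimated correlation). In lung against gut they were mitochondrial RNA in CD4 (0.130 with an estimated correlation) and circulating NK, TGF-beta and classical monocyte in Eff (0.0642 each with an estimated correlation). The immunosuppressive list came to pass in lung against gut monocytes (camera adjusted p = 0.0330). The block changed no other call of a named gene or list.

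Single genes that changed sign had small changes in most cases. In the time course of monocytes and macrophages Trem2 (log2 fold change 0.14) was at -0.021 with no filter and -0.10 to 0.43 with 1 mouse left out. Arg1 was at 0.34 in all tumour mice, 0.99 in antibody mice and -0.37 to 0.10 with 1 mouse left out, and Gpnmb (-0.70) at 0.86, 2.08 and -2.49 to 0.11. In NK cells of antibody mice Emb was at -0.0098 and Ccr2 at -0.012. For Trem2, anti-TREM2 against isotype, monocytes and macrophages (0.02), the values were -0.000193 with cells of at least 1000 counts, -0.10 with untreated mice added, -2.18e-06 with time classes weighted equally, -0.011 with thinned cells and -0.26 to 0.19 with 1 mouse left out. Ifitm1 in the interaction was at -2.29 with cells of at least 1000 counts (5.17). For isotype against untreated, leaving out 1 mouse gave -0.52 to 0.21 for Trem2 and -0.49 to 0.30 for Arg1. Gzma in lung against blood NK cells (-0.12) was at 0.17 with no filter and -0.33 to 0.056 with 1 mouse left out. Trem2 in lung against gut macrophages (-0.11) was at 0.11 with RLE factors, 0.10 with DESeq2 and -1.10 to 0.12 with 1 mouse left out.

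Shares (in percentage points) could not pass an exact test in 4 pairs. All 10 tumour mice gave -2.40 for NK cells from 12H to 36H (5.50 in untreated mice). Past the exact test there were 1.77 for regulatory T cells, 1.08 for migratory DC, 45.1 for dysfunctional and -39.7 for chemotactic NK cells and 33.2 for TAM, over mice annotated with different sets of states. Conventional DC1 was at -0.0690 with cells of at least 1000 counts and -0.423 to 0.682 with 1 mouse left out, and DC2 at -2.12 to 1.96. Between the arms, leaving out 1 mouse gave -4.46 to 1.70 for monocytes and macrophages, -3.50 to 0.243 for CD4 T cells and -7.05 to 6.76 for dysfunctional NK cells, and regulatory T cells were at 0.163 with cells of at least 1000 counts. NK cells in lung against blood (0.931) were at -1.61 with cells of at least 1000 counts and -0.401 in the APC gate. Without pairing by mouse the exact test gives p = 0.0286 for the same differences in gut against blood of B (-14.2), CD4 (-4.14), CD8 (-20.4), NK (-5.09), monocytes (-12.9), neutrophils (-24.2), macrophages (53.7) and DC (9.50). It does so in lung against blood for CD8 (-17.5), monocytes (13.7), neutrophils (-16.1), macrophages (2.36) and DC (5.36), and in lung against gut for CD4 (12.2), CD8 (2.86), NK (6.03), monocytes (26.6), neutrophils (8.05) and macrophages (-51.3).

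Tests of edgeR on cell numbers, as log2 fold changes, passed where exact tests could not. From 12H to 36H they gave 1.2 for dysfunctional and -3.05 for chemotactic NK cells. For anti-TREM2 they gave -0.88 for NK cells, 1.37 for CD8 T cells, 2.32 for DC1, -1.06 for migratory DC, 3.77 for Acp5 TAM, -5.02 for Arg1 TAM, -4.10 for Gpnmb TAM, 3.64 for MoMac1, -2.63 for MoMac2 and 0.97 for monocytes, while dysfunctional NK cells, not past the test, were at 0.0025. Gut against blood had -1.99 for B, -1.53 for CD4, -5.97 for CD8, -4.69 for NK, -2.96 for monocytes, -5.84 for neutrophils, 11.62 for macrophages, 5.17 for DC and -0.49 for stamped cells. Lung against blood had -2.70 for CD8, 0.95 for monocytes, -1.50 for neutrophils, 6.90 for macrophages and 4.47 for DC. Lung against gut had 1.73 for B, 2.54 for CD4, 3.33 for CD8, 4.96 for NK, 3.89 for monocytes, 4.47 for neutrophils, -4.57 for macrophages and -0.76 for DC. The values of macrophages against blood are not sizes, since no blood cell is annotated Macrophages. The tissue shares here and above pool both sorting gates, except where the APC gate is named.

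Not run were any fit of untreated mouse 15, which has no annotation, leaving out a mouse or sums of at least 20 cells in the interaction, sums of at least 20 cells or cells of at least 1000 counts in the CD8 T cell time course, and cells of at least 1000 counts for gut against blood.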

Other observations

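The replication of the time course in antibody mice was tested only after the data were seen.

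Migratory DC of anti-TREM2 tumours held more Il12b, a subunit of the T cell activating cytokine interleukin 12, at 226 ± 15.4 CPM in isotype and 1107 ± 404 CPM in anti-TREM2 mice (log2 fold change 2.25 ± 0.33, adjusted p = 0.00091, n = 3 and 3). Ctsd, a lysosomal protease gene, rose there from 36.01 ± 9.70 to 375 ± 104 CPM (adjusted p = 0.0020). Mitochondrial genes moved in the same cells, 9 of 9 positive (0 calls, 3 higher adjusted over the list alone; camera adjusted p = 0.0040; adjusted p = 0.570 with an estimated correlation). In DC2 the checkpoint ligand gene Pdcd1lg2 fell from 151 ± 29.4 to 14.6 ± 2.50 CPM (adjusted p = 6.5e-05), and in DC1 the focal adhesion gene Zyx from 1292 ± 75.6 to 221 ± 45.0 CPM (adjusted p = 1.5e-05). The dendritic cell maturation list in DC2 had 1 member higher and 6 lower of 15 (1 and 8 adjusted over the list alone; camera adjusted p = 9.5e-08; adjusted p = 0.271 with an estimated correlation). Beside it 4 of 16 dissociation stress genes were higher (6 adjusted over the list alone; camera adjusted p = 0.00088; adjusted p = 0.312 with an estimated correlation).

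In CD4 T cells of anti-TREM2 tumours Birc5, needed for cell division, fell from 194 ± 45.8 to 15.8 ± 27.4 CPM (adjusted p = 0.0043) and the costimulatory receptor gene Tnfrsf9 from 422 ± 134 to 88.6 ± 38.7 CPM (adjusted p = 0.00047). The proliferation list had 4 of 14 members lower (6 adjusted over the list alone; camera adjusted p = 1.7e-08; adjusted p = 0.0903 with an estimated correlation), and 2 of 11 dissociation stress genes were higher (3 adjusted over the list alone; camera adjusted p = 0.00013; adjusted p = 0.0903 with an estimated correlation). In CD4 cells of mice without a tumour, Emb, an adhesion gene, was at 613 ± 507 CPM in blood, 4317 ± 690 in gut and 3084 ± 1212 in lung (n = 4 each; adjusted p = 0.00018 for gut and 0.0024 for lung against blood, the latter 0.0543 without mouse 1).

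The time course was repeated in the 6 antibody mice, which share no library with the untreated mice. In NK cells 117 of 119 measured genes had the same sign, and 86 passed the test with the same sign, where independent lists would share 10.8. Across 1143 genes, which are not independent replicates, the Pearson correlation of the log2 fold changes was 0.692. In monocytes and macrophages 5 of 5 genes had the same sign and 2 passed, with a correlation of 0.289 across 3963 genes.

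Untreated mouse 15 was summed over its wells with at least 500 counts, and the other untreated mice likewise. These wells include ones without a cell type, and the plates of mouse 15 are numbered after those of the antibody mice. Mouse, plate series and cell mix therefore cannot be told apart in these values. Gzma was at 2505 CPM in mouse 15 and at 341 to 1302 in the others, Gzmb at 659 and 226 to 372, Trem2 at 48.4 and 80.3 to 398, Gpnmb at 56.8 and 122 to 363, and Arg1 at 1042 and 102.6 to 1243.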
